A study of Mus musculus with 12 samples.

How the data were processed

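The series holds mRNA sequencing of mouse aorta in 12 samples of 4 groups with 3 files each: WT on a normal diet, and HFD, HAPN and HSAPN on a high-fat diet (60% kcal fat, 12 weeks per the labels). Genotype per the labels was WT in the first 3 groups and APPL1 knockdown in HSAPN. Per the labels, total RNA was extracted with TRIzol and libraries were made with a directional NEB kit. The submitters' processing notes name featureCounts 1.5.0-p3, DESeq 1.8.3 and GRCm38, with no role given for either tool. The aligner, the annotation release and the strand setting are not given in the sources used here, and neither is the meaning of the titles HAPN and HSAPN.

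Each deposited file holds 1 value per gene symbol for 3534 genes, in FPKM as deposited. The unit was checked against exonic lengths of GENCODE M21, since a whole number of reads should return from each value. With 15680000 to 17880000 reads per library, 95.7 to 97.0% of the low values (up to 20 reads, tolerance 0.1) were whole reads. That test does not tell FPKM from a TPM scaling, which would change the read totals and not the whole reads. Read as FPKM, 1 read on a transcript of 1 kb is worth 0.0559 to 0.0638 FPKM. The table holds 12.0 to 17.6% of the reads of a library, so it is part of the transcriptome. The rule that chose its genes is not given in the sources used here. If genes were chosen on these samples, counts and list tests on them are not independent evidence, and every list test compares a list with the rest of this table. Appl1, Appl2, Adipor1, Adipor2 and Nos3 were not analysed here.

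The files of HFD replicates 1 and 2 were identical and entered as 1 library, so 11 distinct libraries were used. A symbol listed 2 times, Dlg2, was left out, and 4 symbols that a spreadsheet had turned into dates were not used as names. Of the symbols, 3410 matched 1 GENCODE M21 gene, 2653 of them protein coding. Pearson r of log2(FPKM + 1) between distinct libraries ran from 0.877 to 0.980.

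Genes with at least 1 FPKM in at least 3 libraries (1659) were tested with limma-trend on log2(FPKM + 1) in limma 3.58.1 under R 4.3.3, in 1 fit with 4 group means and 7 residual degrees of freedom. Tests were called at a Benjamini-Hochberg adjusted p of 0.05 over all tested genes of a comparison. The design allowed for counts or normalized values, and the test written for normalized values was used since the files hold no counts. The pseudocount was 1. Gene lists were tested with camera in limma at its preset correlation of 0.01, with an estimated correlation and with fry beside it, adjusted over the lists of a comparison. Lists with at least 4 tested genes entered, which were 18 of the 37 fixed lists. No gene of 7 fixed lists was in the table. Tables were prepared with pandas 2.3.3 and NumPy 2.4.6 in Python 3.11.15, and figures drawn with matplotlib 3.10.9. Coordinates are those of GRCm38.

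Genes named in the text followed a rule. Eligible were genes with a mean log2(FPKM + 1) of at least 1 whose groups did not overlap, apart from unnamed models, pseudogenes and antibody or T cell receptor segments. Where at least 10 of them passed the threshold in a comparison, the 12 with the highest and the 12 with the lowest log2 difference were to be named, and otherwise the 6 with the smallest p in each direction, as values. Up to 4 genes of each called list with the smallest p were named as well, and Adipoq, Cdh13, Acta2 and Myh11 in every comparison. Ucp1, also on that list, was below the filter. Outside the rule, Gm14202, Igkv12-89 and Ccna1, which passed the threshold, and Bpifa1, Tnnt2 and the genes given for single libraries were chosen after their values were seen. Not every gene that the rule names is described in the text, and the single-gene results of 2 of them are not reported here.

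On data simulated with 1659 genes and 200 changes, the limma test recovered 49.2 to 56.4% of log2 changes of 1, 84.8 to 88.2% of 2 and 92.2 to 93.4% of 3 over the 4 main comparisons, and called 0.51 to 0.7% of unchanged genes. Changed genes were drawn only among those with a mean log2(FPKM + 1) of at least 3, and a further set of genes was shifted by 1. Simulated spreads followed a model and were independent between genes, so these shares are no estimate for the real libraries. Where all arrangements could be listed, list means were compared by exact permutation. Correlations of within-group deviations were tested over all 432 arrangements of libraries within groups. Groups, comparisons, lists, the naming rule and the alternatives for filter, pseudocount, libraries left out, replicate block and list tests were fixed before the data were examined. Chosen after seeing the data were limma-voom on recovered reads, median-ratio scaling, array weights, the marker covariate, the identical libraries counted as 2, the high-fat libraries against WT, and the lists of platelet genes, airway genes, heat shock factor targets, cytotoxic and interferon response genes, and immediate early genes without heat shock genes.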

Results

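The series profiled RNA from mouse aorta in 4 groups. WT libraries came from animals on a normal diet, and HFD, HAPN and HSAPN libraries from animals on a high-fat diet. The labels give HSAPN as a knockdown of APPL1 and give HAPN the same genotype and diet as HFD, so what sets HAPN apart from HFD is not given in the sources used here. The files deposited as HFD replicates 1 and 2 were identical and counted as 1 library, which left 11 distinct libraries: 3 WT, 2 HFD, 3 HAPN and 3 HSAPN. The labels do not say whether replicates came from separate animals, so each p-value measures only the spread between these samples. Appl1 itself was not analysed here, and the knockdown cannot be checked from its target gene.

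Libraries of the same group differed widely in genes of fat, heart muscle and airway. Adipoq ranged from 2.44 to 53.8 FPKM within WT and was 92.6 and 0.174 FPKM in the HFD libraries. The airway gene Bpifa1 stood at 238, 10730 and 2771 FPKM in the WT libraries, at 6438 and 5.84 FPKM in the HFD libraries, and at 840, 3848 and 2.81 FPKM in the HAPN libraries. Tnnt2 was 64.6 FPKM in the library deposited as HFD replicates 1 and 2 and 0.752 FPKM in HFD replicate 3. The 4 groups accounted for 39% of the spread of log2(FPKM + 1) over all tested genes, against 29.7% for random labels (permutation p = 0.107). The first 2 principal components held 36.9% and 26.0% of the variance.

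**Figure D1:**
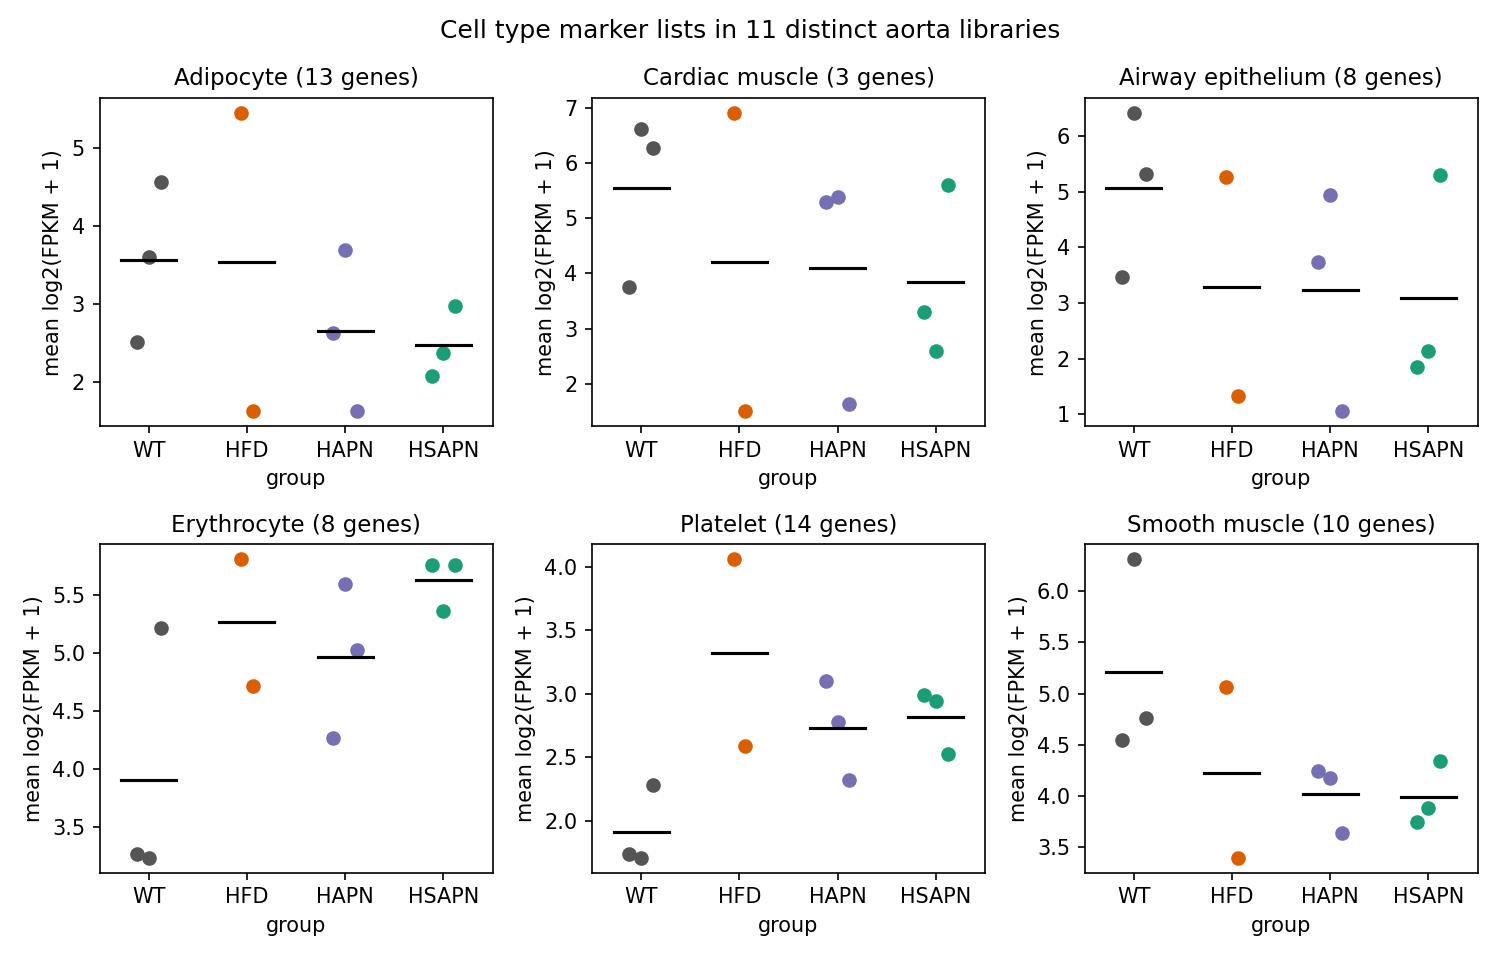
Mean log2(FPKM + 1) of genes of 6 cell or tissue types in each distinct library; each dot is 1 library and each black line the group mean. Axes do not start at 0.

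The high-fat diet was compared with the normal diet through HFD (n = 2) and WT (n = 3). Angptl4, a gene of fat handling, and the platelet receptor gene Clec1b stood higher in HFD, and Egr1 and the clock gene Dbp stood lower, none of them past the threshold. Contractile smooth muscle genes were lower as a list (limma camera adjusted p = 0.00241; adjusted p = 0.847 with an estimated correlation). No single gene changed past the threshold: limma called 0 of 1659 genes, with 189 at an unadjusted p under 0.05 where chance gives 83, and limma-voom also called 0. The smallest adjusted p (limma, Benjamini-Hochberg) was 0.142, for Ctla2a and Nnat. In 320 genes (19.3%, chance 20%) the groups did not overlap.

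The genes with the smallest p-values were read as values. Ctla2a was 38.5 ± 4.29 FPKM in HFD and 10.7 ± 4.52 FPKM in WT (mean ± SD here and below; log2 difference 1.82, SE 0.318, on the log2(FPKM + 1) scale, as are all below), and Nnat was 24.4 ± 9.28 against 7.33 ± 2.22 FPKM (1.59, SE 0.281). Angptl4 was 32.3 ± 5.64 against 7.92 ± 7.02 FPKM (2.17, SE 0.484; limma adjusted p = 0.300). Gng11 was 97.9 ± 1.36 against 47.6 ± 11.7 FPKM, Prg2 4.18 ± 2.20 against 0.432 ± 0.0969 FPKM, and Clec1b 6.73 ± 2.78 against 1.74 ± 1.11 FPKM. In the other direction, Dbp was 3.91 ± 0.588 against 21.4 ± 14.0 FPKM (-1.99, SE 0.472), Egr1 6.80 ± 1.52 against 19.6 ± 10.1 FPKM (-1.30, SE 0.365) and Cyp1a1 0.740 ± 0.632 against 7.75 ± 7.20 FPKM. Log2 differences of Rad51b, Aqp2 and Optc were -0.86, -1.02 and -1.62. Of the genes chosen in advance, Adipoq and Cdh13, which encodes an adiponectin-binding cadherin, overlapped between the groups (log2 -0.26 and 0.12), as did Acta2 (-1.24) and Myh11 (-1.49).

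Among gene lists, 5 were called by camera with its preset correlation. The 9 tested contractile genes were all lower in HFD (median log2 -0.97, limma camera adjusted p = 0.00241; adjusted p = 0.847 with an estimated correlation), among them Cnn1 (82.0 ± 82.2 against 227 ± 185 FPKM), and so were all 8 airway genes (median -1.65), a list written after the data were seen; WT replicate 2 had the highest mean of both lists. Immediate early and heat shock genes were lower in 8 of 10 (median -0.64, limma camera adjusted p = 0.00291, and 0.835 with an estimated correlation), led by Egr1 and by Nr4a1 (12.1 ± 4.81 against 31.3 ± 10.1 FPKM). In lists written after the data were seen, immediate early genes without heat shock genes were lower in 5 of 6 (median -0.81). Heat shock factor targets were higher in 5 of 8 (median 0.28). Erythrocyte genes were higher in 8 of 8 (median 1.62, limma camera adjusted p = 0.00291, and 0.847 with an estimated correlation). A platelet list written after the data were seen was higher in 14 of 14 (median 1.30), and its genes may have been chosen on these values. The erythrocyte median ran from 0.722 to 2.438 over the libraries left out. Fatty acid oxidation genes were higher in 12 of 16 (median 0.31, adjusted p = 0.0317; 0.847) such as Acot2 (12.5 ± 0.693 against 6.28 ± 1.43 FPKM). All 12 tested genes of the mitochondrial genome were lower (median -0.40, adjusted p = 0.0181; 0.847). Adjusted over the list alone, 2 fatty acid oxidation genes passed, against 0 over all genes. No call in any comparison held with an estimated correlation, and none with fry, the self-contained test. Without WT replicate 3 the gene count was 27, without HFD replicate 3 it was 17 and without the library deposited as HFD replicates 1 and 2 it was 1. The contractile median ran from -2.05 without that library to -0.09 without HFD replicate 3, where its call ended (adjusted p = 0.180). Without the library deposited as HFD replicates 1 and 2 the other 4 list calls ended and the fatty acid oxidation median turned to -0.09; that call also ended without WT replicate 2 or 3, and the mitochondrial call without WT replicate 1 or HFD replicate 3.

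With all 8 high-fat libraries set against the 3 WT libraries, a comparison added after the data were seen, the cyclin gene Ccna1, named after its values were seen, was the single gene past the threshold. Its transcript fell from 2.08 ± 0.162 FPKM in WT to 0.394 ± 0.166 FPKM (n = 8; log2 -1.16, SE 0.145, limma adjusted p = 0.0274), or from 63 to 70 reads per library to 5 to 20. At an unadjusted p under 0.05 there were 392 genes where chance gives 83, limma-voom also called 1 gene, limma with array weights 263 and with the high-fat libraries as 1 group 5, and in 67 genes (4%, chance 1.2%) the groups did not overlap. Ctla2a (28.1 ± 7.72 against 10.7 ± 4.52 FPKM, log2 1.40) and Egr1 (5.88 ± 1.19 against 19.6 ± 10.1 FPKM, -1.47) followed, both at a limma adjusted p of 0.103. Clec1b, a platelet receptor, was 5.75 ± 1.47 against 1.74 ± 1.11 FPKM, and Adipoq (log2 -1.30), Cdh13 (-0.10), Acta2 (-1.38) and Myh11 (-1.40) overlapped between the groups. In this comparison the log2 differences and limma tests weigh HFD, HAPN and HSAPN equally as groups. The FPKM means, list means and permutations weigh the 8 libraries equally.

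Erythrocyte genes were higher in 8 of 8 in the high-fat libraries (median log2 1.52, limma camera adjusted p = 3.10e-04; 0.865 with an estimated correlation), and 6 passed adjusted over the list alone against 0 over all genes. Contractile genes were lower in 9 of 9 (median -1.13, adjusted p = 0.00501; 0.865). Markers of other tissues stood lower with them, as values: 8 of 8 airway genes (median -1.74), 9 of 12 general adipocyte genes, and a cardiac list mean of 4.03 against 5.55. Called too were fibroblast genes, lower in 6 of 7 (median -0.60, adjusted p = 0.0357; 0.865), with 4 fibroblast genes passing over the list alone; the fibroblast call ended without WT replicate 1 (0.133) or 3 (0.0530). Without WT replicate 2 the contractile median was -0.69, and over the libraries left out it ran from -1.51 to that value and the erythrocyte median from 1.07 to 2.34 (without WT replicates 2 and 3 in turn). A platelet list, written after the data were seen, was higher in 14 of 14 genes (median 0.97). Its list means were 2.91 and 1.91 (exact permutation p = 0.0121, and 0.111 adjusted by Benjamini-Hochberg over 32 lists). All 14 of its genes were in the table. Genes already seen to be high may have entered the list, so that p is no independent evidence. In a list also written after the data were seen, immediate early genes other than heat shock genes were lower in 6 of 6 tested. List means over 7 genes were 2.90 and 3.66 (exact permutation p = 0.00606, the smallest these libraries can give, and 0.111 adjusted by Benjamini-Hochberg). The list of immediate early and heat shock genes fixed in advance was lower in 6 of 10 and not called (median -0.385, limma camera adjusted p = 0.246). Ccna1 lost its call with median-ratio scaling (limma adjusted p = 0.0607), with a pseudocount of 0.1 (0.112, the highest of its alternatives; the lowest was 0.00504) and without the library deposited as HFD replicates 1 and 2, HAPN replicate 2 or 3, or any HSAPN replicate (0.0605 to 0.109); without any WT replicate it was below the filter. The WT values here and above include WT replicate 3 as labelled. Without it 240 genes passed. Among them, chosen after its values were seen, the hemoglobin gene Hba-a1 stood at 137 and 153 FPKM in WT replicates 1 and 2. It stood at 1198 FPKM in WT replicate 3 and at 1261 ± 444 FPKM in the high-fat libraries.

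HAPN (n = 3) and HFD (n = 2) differed in a heat shock gene. The mean of the inducible chaperone gene Hspa1b rose 19.99-fold. Its neighbour on chromosome 17, Hspa1a, and the cochaperone genes Dnajb1 and Dnaja1 also stood higher without passing the threshold. Of 1659 genes limma called 3, of which 2 were higher and 1 lower; 143 had an unadjusted p under 0.05 and limma-voom called 0. Values were lower in HAPN over the whole table (median log2 -0.24), and median-ratio scaling moved that median by 0.20 to -0.04. In 436 genes (26.3%, chance 20%) the groups did not overlap.

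Hspa1b reached 58.5 ± 35.7 FPKM in HAPN against 2.93 ± 0.620 FPKM in HFD (log2 3.69, SE 0.510, limma adjusted p = 0.0301). Outside the naming rule and chosen after their values were seen, 2 more genes passed. The processed pseudogene Gm14202 rose from 0.198 ± 0.00624 to 3.503 ± 0.768 FPKM (log2 1.90, SE 0.213, adjusted p = 0.0113), which was 1 read in each HFD library and 14 to 21 reads in HAPN. The antibody segment Igkv12-89 fell from 8.51 ± 3.48 to 0.0554 ± 0.0959 FPKM (log2 -3.13, SE 0.452, adjusted p = 0.0301), or from 34 and 59 reads to 0 or 1. Hspa1a was 16.7 ± 10 against 1.41 ± 0.440 FPKM (log2 2.68, adjusted p = 0.0691), Dnajb1 45.8 ± 23.7 against 12.3 ± 2.16 FPKM (1.69, 0.249) and Dnaja1 66.1 ± 16.9 against 25.6 ± 6.71 FPKM (1.32, 0.249). Ahsa2 (1.09) and Dedd2 (0.91) followed. Lower in HAPN were Nnat (6.38 ± 0.611 against 24.4 ± 9.28 FPKM, -1.74, adjusted p = 0.0550), Lypla1 (-0.78), Mmd (-0.94), Tubb4a (-1.001), Ndufb4 (-0.72) and Tmem14a (-0.77). Log2 differences were -1.28 for Adipoq, -0.38 for Cdh13, -0.19 for Acta2 (0.07 with median-ratio scaling) and 0.31 for Myh11, with overlapping groups.

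Immediate early and heat shock genes formed the called list (6 of 10 higher, median log2 0.93, limma camera adjusted p = 1.08e-05, and 0.338 with an estimated correlation), and 4 passed adjusted over the list alone against 1 over all genes. The median of this list ran from 0.573 to 1.159 over the libraries left out. In lists written after the data were seen, heat shock factor targets were higher in 7 of 8 (median 1.24) and immediate early genes without heat shock genes in 2 of 6 (median -0.15). No gene passed with the stricter filter, which left out Gm14202 and Igkv12-89 (Hspa1b limma adjusted p = 0.0593), with limma-voom, with array weights, or with these groups fitted alone (Hspa1b 0.675, the highest of its alternatives; its lowest was 2.52e-04, without HAPN replicate 3). Hspa1b lost its call when any HFD library, HAPN replicate 1 or HAPN replicate 2 was left out. Igkv12-89 lost its call when any HAPN library was left out and with a pseudocount of 0.1 (limma adjusted p = 0.132). Leaving out either HFD library put Igkv12-89 below the filter, which it passed through these libraries and WT replicate 2 (16 reads). Gm14202 lost its call without HAPN replicate 2 (limma adjusted p = 0.0806) or the library deposited as HFD replicates 1 and 2.

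APPL1 knockdown was compared with HAPN (n = 3 each), and 2 inducible heat shock genes were lower in the knockdown libraries. The group that stood apart in these genes was HAPN. Against HFD, heat shock factor targets, a list written after the data were seen, were lower in HSAPN in 7 of 8 by a median log2 of only -0.19. The mean of Hspa1b was 25.5-fold and Hspa1a 18.8-fold lower in HSAPN, and the clock repressor Nfil3 also stood lower. The clock output gene Dbp and the repressor Nr1d2 stood higher. Limma called 2 of 1659 genes, both lower; 130 had an unadjusted p under 0.05, limma-voom called 1, and limma with array weights, which gave HAPN replicate 2 a weight of 4.54, called 79. In 290 genes (17.5%, chance 10%) the groups did not overlap.

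Hspa1b was 2.29 ± 0.266 FPKM in HSAPN against 58.5 ± 35.7 FPKM in HAPN (log2 -3.94, SE 0.456, limma adjusted p = 0.0144). Hspa1a was 0.889 ± 0.144 against 16.7 ± 10 FPKM (log2 -3.02, SE 0.422, limma adjusted p = 0.0341). In single libraries Hspa1b stood at 91.0, 64.2 and 20.3 FPKM in HAPN, at 2.57, 2.03 and 2.28 FPKM in HSAPN, and at 5.22, 8.06 and 8.29 FPKM in WT. Counted in reads, Hspa1b had 150 and 116 in the HFD libraries, against 127, 100 and 106 in HSAPN. Dnajb1 (11.03 ± 0.752 against 45.8 ± 23.7 FPKM, log2 -1.82), Dnaja1 (-1.44) and Nfil3 (3.13 ± 0.344 against 8.08 ± 0.474 FPKM, -1.14) shared a limma adjusted p of 0.143. Higher in HSAPN were Nr1d2 (25.7 ± 3.84 against 12.8 ± 3.10 FPKM, 0.97, adjusted p = 0.147), Dbp (11.6 ± 3.38 against 2.85 ± 0.817 FPKM, 1.70, 0.214), Lypla1 (0.70), Tmem14a (0.72), Emp1 (0.48) and Cyp1a1 (9.36 ± 4.43 against 1.67 ± 1.04 FPKM, 1.92, 0.355). Adipoq (-0.56), Cdh13 (0.08), Acta2 (-0.03) and Myh11 (-0.33) overlapped between the groups.

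Immediate early and heat shock genes were lower in 7 of 10 (median log2 -0.85, limma camera adjusted p = 2.48e-06; 0.266 with an estimated correlation), and 5 passed adjusted over the list alone against 2 over all genes. A list of heat shock factor targets, written after the data were seen, was lower in 8 of 8 (list means 3.41 and 5.14; exact permutation p = 0.1, the smallest that 3 against 3 can give), and immediate early genes without heat shock genes in 3 of 6 (median -0.04). Hspa1b lost its call without HAPN replicate 2 and without each HSAPN replicate in turn, with 0 genes past the threshold in each case and a limma adjusted p of up to 0.116, while its log2 difference lay between -4.56 and -3.50 whichever library of the 2 groups was left out. Hspa1a lost its call in those cases, without HAPN replicate 1 (0.103), with no filter (0.0767) and with limma-voom (0.0892), and with these 2 groups fitted alone neither gene passed (Hspa1b 0.103).

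**Figure D2:**
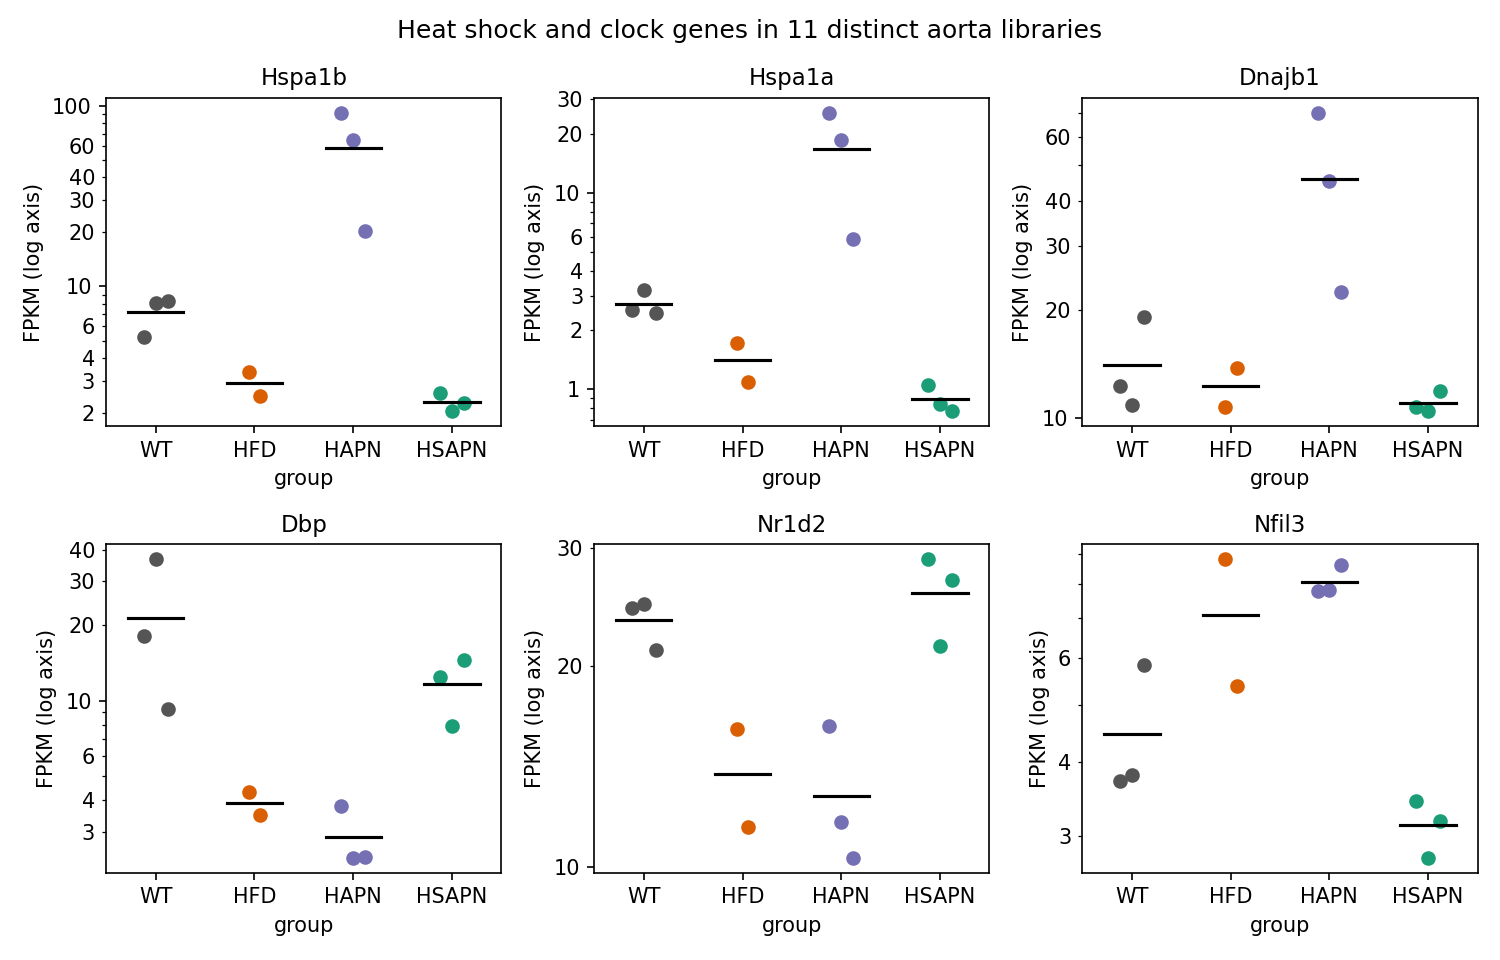
FPKM of 3 heat shock genes and 3 clock genes in each distinct library on a log axis; each dot is 1 library and each black line the group mean. The genes were chosen after their values were seen.

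APPL1 knockdown was also compared with HFD (n = 3 and 2). The titles HAPN and HSAPN share the letters APN, and their meaning is not given in the sources used here. Whatever sets HAPN apart from HFD may therefore also part HSAPN from HFD, and this comparison alone cannot tell it apart from the knockdown. Retnla, the chemokine gene Ccl8 and the clock genes Dbp and Nr1d2 stood higher in HSAPN, none past the threshold. The macrophage list, with 3 of its 15 genes in the table, had a mean of 3.17 against 3.40. Genes of fatty acid oxidation and the respiratory chain were lower as lists (limma camera adjusted p = 0.00167 and 0.00193; 0.622 and 0.724 with an estimated correlation). No gene passed: limma called 0 of 1659, with 67 at an unadjusted p under 0.05 where chance gives 83, and limma-voom called 0. In 328 genes (19.8%, chance 20%) the groups did not overlap. Values were lower in HSAPN over the whole table (median log2 -0.18), and median-ratio scaling moved that median by 0.16.

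Retnla was 1555 ± 1120 FPKM in HSAPN and 165 ± 49.5 FPKM in HFD (log2 2.91), and Ccl8 23.2 ± 8.84 against 8.04 ± 1.11 FPKM (1.36). Cyp1a1 (2.51), Dbp (1.33) and Nr1d2 (0.86) were higher, and Nnat (-1.06), Nfil3 (-0.94), Prg2 (-1.35), Cd209f (-1.19), Fah (-0.50) and Pepd (-0.48) lower, with limma adjusted p from 0.711 to 0.886. Log2 differences were -1.84 for Adipoq, -0.30 for Cdh13, -0.21 for Acta2 and -0.02 for Myh11 (0.17 with median-ratio scaling), with overlapping groups. All 16 fatty acid oxidation genes were lower in HSAPN, such as Acadl, Acot2 and Acadm (median log2 -0.47, limma camera adjusted p = 0.00167; 0.622 with an estimated correlation), as were all 19 nuclear genes of oxidative phosphorylation (-0.39, adjusted p = 0.00193; 0.724). Adipocyte lists, not called, were lower with them: 12 of 12 general adipocyte genes (median -1.25) and 6 of 6 brown adipocyte genes (-0.77). Leaving out 1 library moved the fatty acid oxidation median from -0.85 to -0.16 and that of oxidative phosphorylation from -0.72 to -0.03, and both calls ended without the library deposited as HFD replicates 1 and 2 (0.337 and 0.365), the latter also without HSAPN replicate 1 (0.0675). Cell cycle genes were higher in 7 of 7 (median 0.49, limma camera adjusted p = 4.64e-04, and 0.579 with an estimated correlation). Inflammatory cytokine and adhesion genes were higher in 5 of 5 (0.43, 0.0146 and 0.579 in the same order). Erythrocyte genes were higher in 8 of 8 (0.37, 0.00351 and 0.682) and clock genes in 3 of 4 (0.56, 0.0202 and 0.579). Nfil3 was the clock gene that was lower. Adjusted over the list alone, 3 clock genes passed, counted in either direction, against 0 over all genes. The table held 7 of the 22 cell cycle, 6 of the 20 inflammatory, 8 of the 9 erythrocyte and 4 of the 17 clock genes listed. Lymphocyte genes were higher too: a cytotoxic and interferon response list, written after the data were seen, was higher in 13 of 13 (median 0.78). The T cell list, with 3 of its 13 genes in the table, had a mean of 1.90 against 1.15. Between HAPN and HFD, medians were -0.30 for nuclear oxidative phosphorylation, -0.29 for fatty acid oxidation, 0.29 for cell cycle and 0.47 for inflammatory genes, none called. Between HSAPN and HAPN they were -0.05, -0.11, 0.19 and -0.04, none called. These lists thus stood apart from HFD in HAPN as well, without the knockdown label. Erythrocyte (-0.35 and 0.68) and clock genes (-0.05 and 0.61) differed more between HSAPN and HAPN, also not called. Over the libraries left out the cell cycle median ran from 0.276 to 0.675. With median-ratio scaling the inflammatory (0.0665) and clock (0.0573) calls ended, as both did without the library deposited as HFD replicates 1 and 2, the inflammatory call with the marker covariate (0.0742), and the clock call without HFD replicate 3 or HSAPN replicate 1. Without HFD replicate 3 the erythrocyte median was -0.05 and 3 genes passed, and without the library deposited as HFD replicates 1 and 2 1 gene passed.

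The difference of HSAPN from HAPN ran opposite to that of HAPN from HFD for Hspa1b, the 1 gene called in opposite directions. With the stricter filter 0 genes were called in opposite directions. Over all genes the log2 differences of these comparisons correlated at r = -0.51. Simulated data without any change gave a mean of -0.42 (SD 0.412), since both comparisons use the HAPN libraries. The differences of HAPN from HFD and of HFD from WT correlated at r = -0.31 against a mean of -0.58 (SD 0.33) in such data, with 0 genes called in opposite directions by limma. Each correlation lay within 1 SD of its simulated mean, so neither stands apart from data without change. Across all 4 groups the limma F test called 2 genes, Hspa1b and Gm14202.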

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

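Chosen after the results were seen were median-ratio scaling, limma-voom, array weights, identical libraries counted as 2, the marker covariate, the second replicate block, and the high-fat comparison with its 1-group form. Numbers of genes past the threshold follow the order HFD/WT, HAPN/HFD, HSAPN/HAPN, HSAPN/HFD, high-fat/WT, and any difference among the 4 groups: 0, 3, 2, 0, 1 and 2 as reported (limma; unadjusted p under 0.05: 189, 143, 130, 67 and 392 for the first 5). They were 0, 5, 3, 0, 0 and 2 with median-ratio scaling, 2, 5, 1, 2, 3 and 4 with no filter (3506 genes tested), 0, 0, 2, 0, 1 and 2 with a stricter filter (at least 50 recovered reads in 3 libraries; 1559 genes), and 0, 2, 2, 0, 0 and 2 with pseudocount 0.1. With the replicate number as a replicate block they were 0, 0, 3, 0, 1 and 1, and with the replicate block with the HFD library numbered 2, 1, 3, 3, 1, 0 and 2; correlation between libraries sharing a number ran from -0.592 to 0.499 over 15 pairs, 4 of them above 0.1. Under that replicate block Ccna1 (limma adjusted p = 0.0963; 0.0536 with the second numbering) and, in HAPN/HFD, Hspa1b (0.0795; 0.0705) were not called, nor were Gm14202 and Igkv12-89 with the first numbering (0.0574 each), so the gene counted in high-fat/WT there is not Ccna1. They were 0, 0, 1, 0, 1 and 0 with limma-voom on recovered reads, 0, 0, 79, 0, 263 and 264 with array weights (weights from 0.4 to 4.54, HAPN replicate 2 at 4.54), 6, 10, 2, 2, 8 and 8 with the identical HFD libraries counted as 2, and 0, 5, 2, 0, 2 and 1 with the marker covariate. Only the libraries of the 2 groups gave 0 in each of the 4 comparisons, and the 8 high-fat libraries as 1 group gave 5. HAPN/WT and HSAPN/WT, added after the data were seen, gave 0 genes each by limma (368 and 360 at an unadjusted p under 0.05). The cause of these changes was not tested, beyond the genes or libraries removed.

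Leaving out 1 library moved the counts from 0 to 27 for HFD/WT (27 without WT replicate 3), 0 to 5 for HAPN/HFD, 0 to 3 for HSAPN/HAPN, 0 to 3 for HSAPN/HFD, 0 to 240 for high-fat/WT and 0 to 53 for any difference (240 and 53 without WT replicate 3). An arm left with 1 HFD library is assumed to vary like the other groups. Lists called numbered 5, 1, 1, 6 and 3 for HFD/WT, HAPN/HFD, HSAPN/HAPN, HSAPN/HFD and high-fat/WT. In that order they were 5, 1, 2, 5 and 3 with median-ratio scaling, 6, 2, 3, 6 and 3 with the stricter filter, 5, 1, 1, 6 and 3 with pseudocount 0.1, 6, 1, 1, 7 and 4 with the replicate block, 4, 4, 1, 5 and 3 with the HFD library numbered 2 in it, and 5, 1, 2, 5 and 4 with the marker covariate. They were 0 in each of the 5 comparisons with an estimated correlation and with fry, and ranged over libraries left out from 3 to 5, 1 to 5, 1 to 3, 3 to 9 and 3 to 5.

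Of 126 named gene results, 721 leave-one-out values kept direction and side, 28 gained and 24 lost the call and 24 reversed; under other alternatives 1286 kept, 51 gained, 22 lost and 14 reversed. Of 16 list results, 80 leave-one-out values kept, 17 lost and 2 reversed, and 90 others kept and 37 lost. Reversed values (log2) were, with median-ratio scaling, Acta2 0.067 in HAPN/HFD and Myh11 0.17 in HSAPN/HFD; with the replicate block, Adipoq 0.051 in HFD/WT; with the HFD library numbered 2, Cdh13 -0.072 in HFD/WT and Myh11 0.12 in HSAPN/HFD; with array weights, Cdh13 -0.10 in HSAPN/HAPN; with the identical HFD libraries counted as 2, Adipoq 0.80 in HFD/WT and Myh11 -0.067 in HAPN/HFD; and with the marker covariate, Adipoq 0.61 in HFD/WT, Acta2 0.049 in HSAPN/HAPN, Acta2 0.033 and Myh11 0.29 in HSAPN/HFD, and Adipoq 0.08 and Cdh13 0.18 in high-fat/WT. Leave-one-out ranges that crossed 0 were, in HFD/WT, Cdh13 -0.50 to 0.74, Adipoq -3.42 to 2.90 and fatty acid oxidation genes -0.089 to 0.62; in high-fat/WT, Cdh13 -0.49 to 0.15; in HAPN/HFD, Adipoq -4.44 to 1.88, Cdh13 -1.0 to 0.24, Acta2 -1.02 to 0.65 and Myh11 -0.81 to 1.43; in HSAPN/HFD, Adipoq -4.99 to 1.32, Cdh13 -0.92 to 0.32, Acta2 -1.05 to 0.62, Myh11 -1.14 to 1.10, Slc4a1 -0.066 to 0.91, Bpgm -0.025 to 0.52 and erythrocyte genes -0.046 to 0.90; and in HSAPN/HAPN, Acta2 -0.26 to 0.21, Adipoq -1.55 to 0.42 and Cdh13 -0.013 to 0.23. The correlations between comparisons were -0.28 and -0.46 with the stricter filter. The alternatives written for counts (DESeq2 size factors and test, library size alone) were not run, since the values are not counts and are already scaled; the level of Appl1 was not analysed here. At this depth 1 read on a transcript of 1 kb is worth 0.0559 to 0.0638 FPKM.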

Other observations

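The tests of handling stress, of shared reads, of diet and of the correlation between tissues, the test of the hour, the comparison of all high-fat libraries with WT, and the values of WT replicate 3 and HAPN replicate 3 were chosen after the result was seen.

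Heat shock genes were higher in HAPN than in HSAPN. Fat and heart tissue from beside the aorta is argued against as the whole cause, since its markers hardly differed in mean between these groups. List means in HAPN and HSAPN were 2.65 and 2.47 for adipocyte genes and 4.1 and 3.84 for cardiac genes. Single libraries spread widely, with cardiac values from 1.63 to 5.39 in HAPN and from 2.59 to 5.61 in HSAPN. With the mean of these markers as a covariate the median difference of 8 heat shock factor targets was 0.99 times that without it (1.45 and 1.47). Limma still called Hspa1b (adjusted p = 0.00515) and Hspa1a (adjusted p = 0.0200). Such close means largely fix that ratio in advance, so it adds little. Other adjacent tissue was not tested. Reads shared between Hspa1a and Hspa1b are argued against as the whole cause too, since the other 6 targets were higher in 6 of 6, by a median log2 of 1.27 (0.22 to 1.82). The target list was written after the data were seen, and 8 of its 20 genes were in the table. Whether the calls of Hspa1a and Hspa1b are 1 signal through shared reads was not tested. Handling stress cannot be told apart: 6 immediate early genes went both ways (3 higher, 3 lower, median log2 0.036, from -0.40 to 1.20), and a stress that spares them may still be the source. Genotype alone, as labelled, does not part the libraries in this way either, since HFD and WT share the genotype of HAPN and held Hspa1b at 2.49 and 3.36 and at 5.22 to 8.29 FPKM; what sets HAPN apart stays open, and a joint effect was not tested.

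Markers of fat, heart muscle and airway differed between libraries of the same group and moved together. Diet was the same within each group as labelled, so the design alone leaves it out for these differences; the adipocyte list means of the 2 HFD libraries lay 3.83 log2 units apart and those of WT spanned 2.06. Differing amounts of adjacent tissue in the dissected piece may be a candidate explanation: within-group deviations of adipocyte and airway lists correlated over the 11 libraries at r = 0.839 (exact p = 0.0116; Benjamini-Hochberg 0.0174 over 3 relations), of adipocyte and cardiac lists at r = 0.899 (exact p = 0.0208; 0.0208) and of cardiac and airway lists at r = 0.957 (exact p = 0.00694; 0.0174). Without the 2 libraries farthest out, r was 0.80, 0.82 and 0.94. These lists share 0 genes, the airway list was written after the data were seen, only 3 cardiac genes were in the table, its genes may have been chosen on these libraries, and the study's tissue label names aorta alone.

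The clock genes Dbp and Nr1d2 had lower values in HFD and HAPN than in WT and HSAPN, by 1.85 and 0.85 on the log2 scale, a pattern noticed in the data. Neither gene passed in any comparison (limma adjusted p = 0.214 and 0.147 in HSAPN/HAPN), and the clock list was called by camera in HSAPN/HFD alone (0.0202; 0.579 with an estimated correlation), not in HFD/WT (0.0575) or HSAPN/HAPN (0.643). Fat and heart tissue is argued against as the whole cause, since its markers did not part the groups in this way. Adipocyte list means were 3.56 in WT and 2.47 in HSAPN, against 3.54 in HFD and 2.65 in HAPN. Cardiac list means were 5.55 and 3.84 against 4.2 and 4.1. The mean difference with the marker covariate was 0.99 times that without it (1.33 and 1.35), a ratio that such means largely fix in advance. Single libraries spread widely around these means, with adipocyte values of 5.45 and 1.62 and cardiac values of 6.91 and 1.5 in HFD. In the clock list both HFD libraries, at 2.91 and 2.47, still lay below all WT libraries (3.13 to 3.75). HSAPN, at 2.85 to 3.24, overlapped with HFD. Other adjacent tissue was not tested. The hour of tissue collection cannot be told apart from the groups, since the labels give no hour; Nfil3 differed the other way, by -0.848, and Hlf by 0.39. Neither diet alone nor genotype alone, as labelled, parts the libraries in this way, since HSAPN shared its diet with HFD and HAPN, and WT shared its genotype with them; a joint effect was not tested.

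Splits of the libraries were counted. For HSAPN/HAPN the real split of the 6 libraries gave 2 genes and the highest of the others gave 0; the real split was 1 of 10, too few for a share under 0.05. For any difference among the 4 groups, 8 of 100 splits of the 11 libraries gave as many genes as the real 2, and the highest other gave 26, so chance is not excluded. Of the other splits, 3 called more than 10 genes and 87 called 0. The 3 may point to a structure among the libraries, which was neither tested nor identified. For high-fat libraries against WT, 14 of 100 splits gave as many as the real 1 and the highest other gave 6, so chance is not excluded there either.

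Without WT replicate 3, 240 genes passed in the high-fat comparison (132 higher, 108 lower), against 1 with it. The genes below were chosen after their values were seen, from those that passed without it. That choice favours genes in which WT replicate 3 lies near the high-fat libraries, so their values do not test its label. Neither a wrong label nor a different blood content of WT replicate 3 was tested, and every WT mean includes it as labelled. Hbb-bt stood at 38.1, 32.6 and 318.5 FPKM in WT replicates 1, 2 and 3 and at 316.4 ± 104 FPKM in the high-fat libraries, Lrrk2 at 2.56, 2.29, 9.65 and 9.18 ± 2.23 FPKM, and Mapk13 at 34.6, 30.2, 15.5 and 13.7 ± 1.45 FPKM. Egr1 was 16.4, 30.9 and 11.4 FPKM in WT against 5.88 ± 1.19 FPKM.

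HAPN replicate 3 held high values of Cxcl10 (41.8 FPKM), Gzmb (30.6 FPKM), Ubd (37.5 FPKM) and Igtp (108.0 FPKM), and a list of cytotoxic and interferon response genes averaged 4.53 there against 0.99 to 3.31 in the other libraries. Retnla stood at 430.6, 1570 and 2665 FPKM in the HSAPN libraries. HFD replicate 3 held Gm23935 at 110600 FPKM. Ucp1 was 9.03 FPKM in the library deposited as HFD replicates 1 and 2.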
